A study of Homo sapiens with 87 samples.

How the data were processed

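Ribosome-protected fragments were sequenced from HEK293 cells that had received reporter mRNA or plasmid, and from cells without an analysed reporter profile. Per the labels' protocol, 8 µg of mRNA was given for 8 h or 1 µg of plasmid for 24 h, lysates contained cycloheximide at 100 µg/mL and were digested with 750 U of RNase I per 100 A260 units, and monosome (25 to 35 nt) or disome (40 to 60 nt) fragments were cut from a gel. The library preparation used poly(A) polymerase, which adds A residues to fragment ends. The submitters' processing notes name bcl2fastq 2.20.0.422, cutadapt 2.8, Bowtie 1.2.3 and STAR 2.7.10a. The genome build, read length filter and A-site offset are not given in the sources used here.

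The authors deposited 2 kinds of files. Reporter tables hold whole-number footprint counts per nucleotide position of the reporter, as deposited and without normalization; how fragments were assigned to positions is not given in the sources used here. The genome-wide tables hold a signal per codon that the authors deposited for each transcript, and 3 times each value was whole within 9.09e-13, so the value was read as the mean of 3 nucleotide counts and multiplied by 3. Every genome-wide table was empty in the first 15 and the last 10 codons, and these were left out. Totals and depths are in the report. Intervals cover counting error only, since fragments amplified by PCR without molecular identifiers are not independent.

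Libraries were grouped by their sample labels. Whole-series tables had 33 columns, and 4 of them matched no sample and were not used. Of the Arg libraries 4, 1 of the Arg IV libraries and 1 SAMD9 library per arm came from columns that show a group but no replicate number. One of the Arg columns names HEK293T while the labels say HEK293. Columns named "middle mutation" and "T-C" were assigned through the codons in their tables' names. Chi-square tests over bins of 3 positions separated all 15 pairs of Arg libraries and the pair of Arg IV libraries beyond sampling noise, so none was counted as a duplicate. Tables fell into 15 runs by the dates in their names. Per the names of the genome-wide tables, the 3 control libraries came from different experiments (1 general, 1 on SAMD9 and 1 on SAMD9L), and the cells with and without Arg carried an Arg reporter.

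Reporter sequences were not used here. The variable segment was taken to start where the mean correlation of log2 profiles between 17 reporters of full length, in windows of 27 nt, first fell below 0.5 (position 102, counted from 0 as in the files) and to end 21 nt before the terminal peak at position 257. The upstream segment was the 60 nt before it (42 to 101) and the terminal segment ran from 237 to 265. Shorter reporters were shifted by 27 nt (Met and Phe) or 33 nt (Trp). Positions that share the phase of the upstream and terminal peaks were called the main frame, and the next 2 positions the +1 and -1 frames. The segment borders, the smallest number of 20 disome footprints and the positions named in the report were set after the profiles were seen. Shares carry Wilson 95% intervals and differences of shares Newcombe intervals. Ratios within 1 library carry Wilson intervals turned into odds, and ratios between libraries log-normal intervals. Differences between libraries in the gain of a frame carry intervals from the normal approximation. Named Arg positions were also given per upstream footprint, because shares of 1 segment are tied to each other. The Arg gain in +1 share was tested with an exact sign-flip test, chosen after its values were seen. Replicated groups were compared with an exact two-sided permutation test and correlations with 100000 permutations.

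Codon occupancy used transcripts with at least 100 counts, and its interval came from 200 bootstrap resamples of transcripts. The yardstick was the SD between the 3 control libraries. Runs were compared with 10 codons on each side. Transcript ratios used log2 of CPM plus 1, with no p-value, since each arm had 1 library. Reading frame in the genome-wide libraries had been planned, but values per codon hold none, and density around runs was used in its place. The planned tests of SAMD9 induction and its replicate block needed 2 libraries per arm. Of 18228 transcripts 0 matched a gene name in the reference table, so the 15 gene lists fixed beforehand were not analysed here.

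The rule for named items was fixed before the data were examined. It covers the 6 Arg and 2 Phe codons, the 5 codons with the highest and the 5 with the lowest ratio, every reporter, run types with at least 1000 counts in each library, and the transcripts with the largest changes, of which at most 2 in each direction are printed because they have no names. Scripts were tested on simulated counts built from the SAMD9 control library. Log2 changes of 3 for the Phe codons, 2 for CGT and -1 for GGC were recovered as 2.94, 2.02 and -0.98 over 3729 transcripts. Of 200 transcripts changed 4-fold, 70.5% passed the rule among 5362, with 0 false calls. The rule misses transcripts whose control libraries differ widely. Because the simulated counts came from 1 library, the 0 false calls do not measure false calls between real libraries. Alternatives left out window edges, top positions, replicates or controls, and changed the occupancy weighting, site, cap, run length, filter, pseudocount and scaling (TMM from edgeR 4.0.16 in R 4.3.3). Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.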

Results

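Ribosome profiling was carried out in HEK293 cells, a human embryonic kidney line, and 87 samples in 77 groups were labelled. The method sequences the pieces of mRNA that ribosomes protect from RNase, so the position of each footprint marks a ribosome. Most samples measured a transfected reporter carrying a run of one amino acid, 7 measured the cells' own mRNAs, and 28 disome libraries sampled the longer footprints of 2 collided ribosomes. The 50 monosome reporter libraries held 390 to 34750 footprints (median 4026) and the disome libraries 1 to 23969 (median 82). The 7 libraries of the cells' own mRNAs held 1377464 to 8852210 A-site counts. Except for the Arg reporter (6 libraries), the Arg reporter labelled IV (2) and the cells labelled HEK293 control (3), each condition had 1 library that could be used, so its intervals are 95% Wilson or log-normal counting intervals that leave out variation between transfections. Labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these samples. For the Phe reporter in SAMD9 cells 2 replicates per arm are labelled, but only 1 column per arm was found.

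The first comparison asked where ribosomes sat on reporters that differed in the repeated amino acid. Ribosomes filled the repeat region very unequally. The variable segment, where the reporters' profiles differ, took 73.1% of the footprints of the upstream, variable and terminal segments on the Trp reporter (95% interval 71.6 to 74.6) and 63.7% on Glu (62.4 to 64.9), against 2.10% on Ala (1.65 to 2.67) and 2.63% on Gly (2.08 to 3.31). The median over 20 amino acids was 33.3%. The Arg reporter averaged 38.7% ± 9.11 (SD, n = 6), with single libraries between 24.4% and 52.9%. These Arg libraries came from several runs, while 18 of the 19 other reporters shared 1 run with an Arg library. No reporter was replicated within that run. A difference between 2 single-library reporters of less than about that range was thus not separable from variation between libraries.

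The reporters also differed in the footprints at the shared peak near the end of translation. Terminal footprints per upstream footprint were lowest on the Asp reporter, at 0.0495 (0.0425 to 0.0577), followed by Glu at 0.164 (0.145 to 0.186) and Lys at 0.189 (0.170 to 0.210). They were highest on Trp, at 1.03 (0.901 to 1.17), and Ser, at 1.03 (0.953 to 1.11). Arg gave 0.490 ± 0.130 (SD, n = 6). The Ala and Gly reporters, almost empty in the variable segment, still had 0.287 (0.264 to 0.313) and 0.388 (0.356 to 0.423) terminal footprints per upstream footprint. The segment borders were set from the profiles, since reporter sequences were not used here, and a peak cannot be assigned to a codon.

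**Figure D1:**
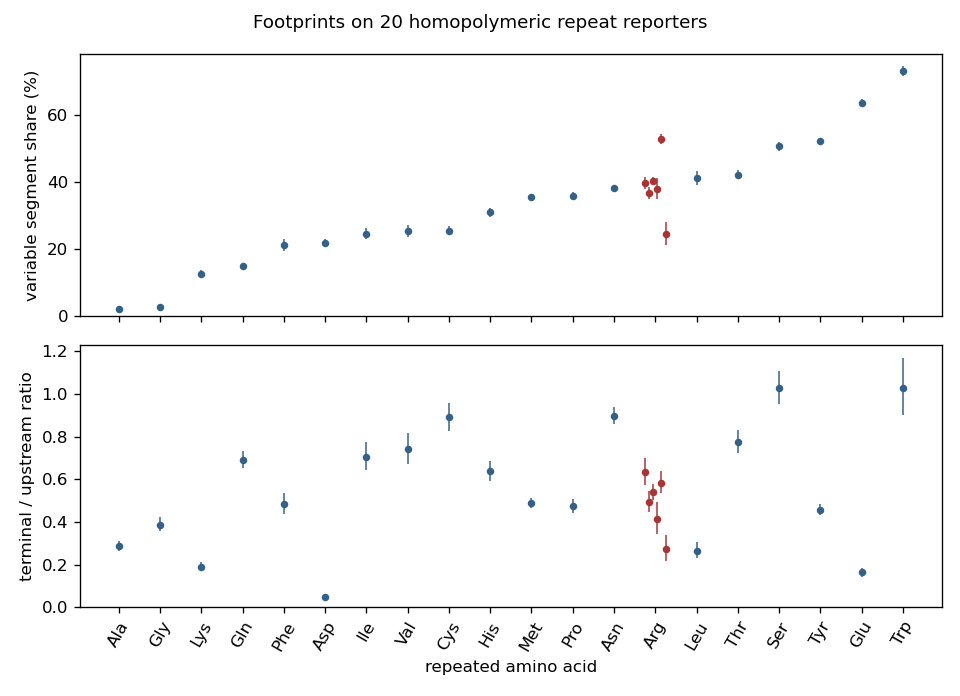
Share of footprints in the variable segment (upper panel, %) and terminal to upstream ratio (lower panel) for 20 reporters, ordered by the mean share. Points are libraries with 95% counting intervals, Arg (6 libraries) in red; shares run from 2.10% for Ala to 73.1% for Trp.

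Reading frame was compared between the variable and the upstream segment of the same library, because the upstream frame shares differed between runs. The Gln reporter moved most in the -1 direction, from 12.2% of upstream to 37.4% of variable footprints, a gain of 25.2 points (21.9 to 28.6). In the +1 direction the Gly reporter gained 38.0 points (26.7 to 49.7) on only 69 variable footprints, Met gained 13.8 (11.8 to 15.8), Ile 13.6 (9.14 to 18.1) and Val 11.3 (6.74 to 16). Ser lost 15.6 points of +1 share, with an interval of -18.0 to -13.3. Single sites carried some of these gains. Without the top position of the variable segment the +1 difference was -0.33 points (-2.23 to 1.60) for Met and 3.72 (-0.60 to 8.22) for Ile, so neither was detectable, while Gln kept 20.3 points (17.0 to 23.8), Gly 28.6 (17.6 to 41.4) and Val 14.4 (9.55 to 19.3). Without the top position of both segments Met and Ile turned to -10.7 (-12.9 to -8.52) and -7.24 points (-12.2 to -2.18), Ser went to -23.4, and Gln and Gly fell to gains of 15.2 and 24.4. Of 19 reporters with 1 library, 10 had a +1 share above upstream beyond the counting interval and 7 below, with all positions included. The Arg reporter gained 7.91 ± 7.11 points (SD, n = 6), above upstream beyond the counting interval in 5 libraries and below in 1 (range -3.09 to 16.7). An exact two-sided sign-flip permutation test over the 6 libraries gave p = 0.0625, where the smallest p it can give is 0.0312. Without the top position of the variable segment, an alternative chosen after seeing the data, the mean gain was 14.2 points, with the smallest p that this exact test can give. That position was in the main frame in each Arg library, so leaving it out raises the +1 share by construction. Without the top position of both segments the mean gain was 7.71 points (exact p = 0.125).

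Footprints beyond the terminal peak were more frequent on the Arg reporter than on the 18 others of a shared run. They amounted to 5.89% ± 2.22 of upstream footprints (SD, n = 6; range 3.04 to 9.68), against 0.298% for Ala to 2.63% for Phe among the 19 other reporters. In that run, which held 18 of those others, the Arg library had 5.07% (3.98 to 6.47) and no other upper bound went above 3.79%. Levels of 1 reporter differed between libraries, as the Phe reporter in SAMD9 cells without Dox had 7.92% (4.79 to 13.1, 16 footprints), within the range of the Arg libraries, against 2.63% (1.82 to 3.79) in the shared run. Over the 6 Arg libraries 66.9% of these footprints (62.3 to 71.2) were in the +1 frame, compared with 49.7% (44.7 to 54.8) over the other reporters together. This difference in frame did not hold within the shared run, where the +1 share was 45.6% (34.3 to 57.3) for Arg and 50.1% (45.0 to 55.2) for the 18 others pooled. The Arg libraries of the other runs had 70.9% (66.0 to 75.4).

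**Figure D2:**
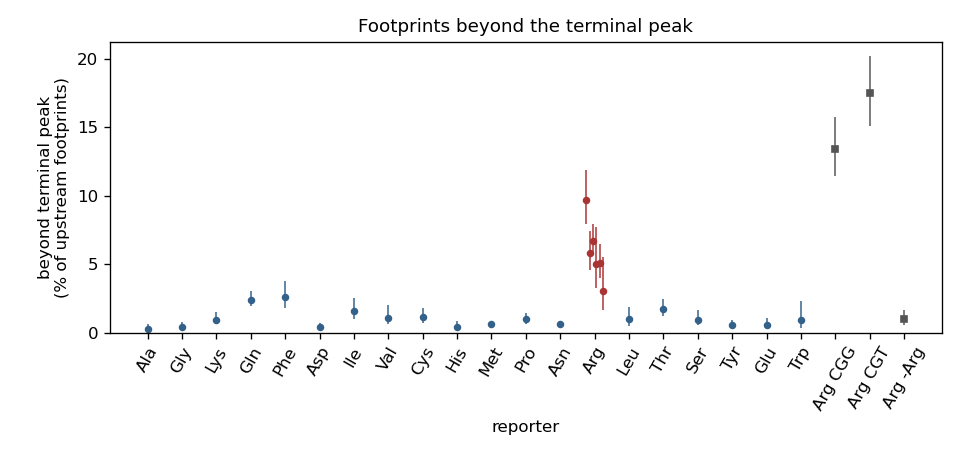
Footprints beyond the terminal peak as a percentage of upstream footprints, by reporter, with 95% counting intervals; Arg libraries in red and the CGG, CGT and Arg withdrawal libraries as squares. The Arg libraries lie between 3.04% and 9.68%, CGT is at 17.5% and the library without Arg is at 0.979%.

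The next comparison asked what the lack of an amino acid did on a reporter that repeats it. In the library without Arg, ribosomes were concentrated near the start of the Arg reporter's variable segment and terminal footprints were fewer. Position 116 held 60.8% of variable-segment footprints (58.9 to 62.6) without Arg, against 20% (17.6 to 22.5) in the library of the same table. Per upstream footprint position 116 held 1.19 (1.11 to 1.28) without Arg and 0.173 (0.149 to 0.200) with it, while position 164 did not differ detectably, at 0.133 (0.114 to 0.155) and 0.132 (0.112 to 0.156). The variable-segment share was 62.4% (61 to 63.8), above all 6 unstarved libraries and 2.61 SD above their mean. Against the library of the same table the terminal to upstream ratio was 2.75-fold lower (log2 ratio -1.46, -1.70 to -1.22), and footprints beyond the terminal peak were 5.94-fold lower (log2 ratio -2.57, -3.41 to -1.73).

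Lys withdrawal gave the largest difference in variable-segment share of the 6 amino acids, while the log2 ratio of terminal to upstream, -1.03, was smaller in size than that of Arg, -1.46. The variable-segment share of the Lys reporter was 75.5% (74.5 to 76.5) without Lys and 12.6% (11.4 to 13.8) with it, a difference of 62.9 points (61.3 to 64.4), and the terminal to upstream ratio was 2.04-fold lower. Withdrawal of Met raised the share by 12.8 points (11.2 to 14.3) and the ratio was 1.95-fold lower. Phe withdrawal raised the share by 18.2 points (14.1 to 22.4) with a log2 ratio of terminal to upstream of -0.04 (-0.39 to 0.30), a change not detectable at this depth, and of 0.39 without the top position of each window. The share was lower without Cys and without Leu, with differences of -7.48 points (-9.60 to -5.31) and -9.87 points (-13.4 to -6.22). The log2 ratio of terminal to upstream was -0.46 (-0.63 to -0.28) for Cys, and 0.0275 without the top positions, and 0.64 (0.32 to 0.95) for Leu, and 0.32 without them. Apart from Arg, the starved and unstarved libraries came from different runs, so run and withdrawal cannot be told apart. The share differences for Cys, Leu, Met and Phe are smaller than the range of the Arg libraries (24.4% to 52.9%), and that for Lys is larger. For Arg the difference from the library of the same table, 25.7 points, is also smaller than that range, although the starved share of 62.4% lies above it. Without the top position of each window in both arms the Arg share difference was 2.02 points, with an unstarved mean of 49.9%.

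**Figure D3:**
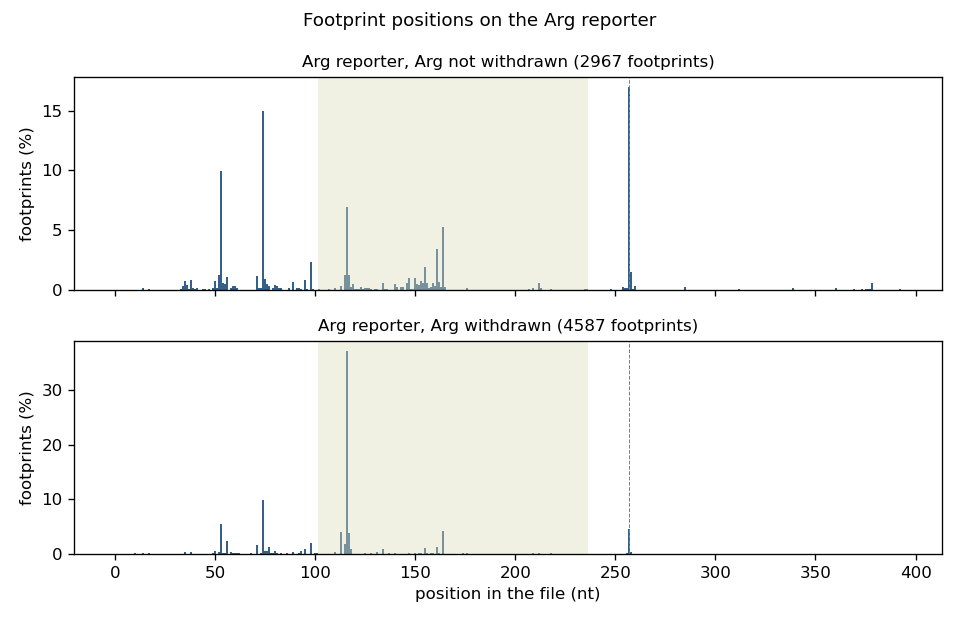
Footprints per position (% of the library) on the Arg reporter with (2967 footprints) and without Arg (4587 footprints), libraries of the same table. The shaded part is the variable segment and the dashed line the terminal peak at position 257; position 116 rises to 60.8% of variable-segment footprints without Arg.

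SAMD9 is an antiviral protein whose active form cleaves the tRNA for Phe, and its induction with Dox was followed on the Phe reporter. The library with Dox had fewer terminal footprints per upstream footprint. The terminal to upstream ratio was 0.101 (0.0737 to 0.140) with Dox and 0.322 (0.244 to 0.425) without, 3.17-fold lower (log2 ratio -1.66, -2.28 to -1.05), and footprints beyond the terminal peak, 1.24% of upstream ones with Dox and 7.92% without, were 6.40-fold lower (log2 ratio -2.68, -4.15 to -1.21). The share in the variable segment did not differ detectably, at 40.0% and 37.0% (difference 3.0 points, -2.84 to 8.71), and neither did the gain in +1 share (difference 2.2 points, -6.03 to 10.4). The libraries held 768 and 452 footprints, and with 1 of the 2 labelled replicates per arm found, no permutation test was possible.

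The Pro reporter was compared with and without depletion of eIF5A, the factor that eases peptide bond formation at prolines, and ribosomes were more concentrated at a single site in the knockdown library. Position 110 held 76.5% of variable-segment footprints (74.4 to 78.5) after knockdown and 69.7% (65.4 to 73.6) with the scramble control. The variable-segment share was 65.7% (63.8 to 67.5) after knockdown and 50.9% (47.7 to 54.1) with scramble, a difference of 14.8 points (11.1 to 18.5). A difference in the terminal to upstream ratio was not detectable at this depth, with a log2 ratio of 0.40 (-0.12 to 0.93). Without the top positions the share difference was 4.92 points. Both libraries came from the same run, 1 per arm, and no test was made. The Pro reporter library of another run, with no depletion labelled, had 51.3% (49.0 to 53.6) at position 110 and a share of 35.8%, so the difference between knockdown and scramble was no larger than that between these 2 libraries without knockdown.

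Variants of the Arg reporter carried codon names or IV in their labels. The libraries labelled IV had more terminal footprints per upstream footprint, 0.913 ± 0.141 (SD, n = 2) against 0.490 ± 0.130 (SD, n = 6), a difference of 0.424. The exact two-sided permutation test gave p = 0.0357, the smallest its 28 splits can give, and 0.0714 after Benjamini-Hochberg adjustment over 4 measures. The +1 frame share in the last of 4 equal parts of the variable segment was higher by 38.2 points, with the same exact p = 0.0357 and adjusted p of 0.0714. This measure was not planned and the other parts were not tested, so the adjustment does not cover a choice among the parts. The Arg libraries held only 18 to 88 footprints in that part, and the IV libraries 298 and 460. The variable-segment share, lower by a difference of -8.56 points, had an exact permutation p = 0.286 (n = 2 and 6). Without the top position of each window the difference in the terminal to upstream ratio was 0.141. In the run that held a library of each kind, the log2 ratio of terminal to upstream was 0.72 (0.55 to 0.89). No result in this family passed the adjusted threshold. Outside these 4 measures, and not tested, the peaks of the Arg libraries were nearly absent from both IV libraries. Per upstream footprint position 116 held 0 and 0.0036 there, and position 164 held 0.0029 and 0.0036. The 6 Arg libraries ranged from 0.0552 to 0.392 at position 116 and from 0.0994 to 0.412 at position 164. Both positions were chosen as peaks of the Arg libraries.

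The Arg reporters labelled with codons differed in the height of the peak at position 164. In the variant labelled CGCCGC-CGGCGG the peak at position 164 held 3.14% of variable-segment footprints (2.31 to 4.26), while position 116 held 46.9% (44.1 to 49.6). In the variant labelled AGC, position 164 held 45.9% (44.2 to 47.7) and position 116 held 7.92% (7.03 to 8.91). AGC codes for Ser and not for Arg, so what was changed in that reporter cannot be read from its label. Per upstream footprint position 164 held 0.0217 (0.0158 to 0.0298) in the former and 0.821 (0.766 to 0.880) in the latter, below and above all 6 Arg libraries (0.0994 to 0.412), while position 116 lay within their range in both, at 0.324 and 0.142. Footprints beyond the terminal peak were 13.4% of upstream ones for CGG (11.5 to 15.8) and 17.5% for CGT (15.1 to 20.2), both above all 6 Arg libraries, while AGC at 7.19% (6.01 to 8.60) and CGCCGC-CGGCGG at 5.51% (4.50 to 6.75) lay within the range of the Arg libraries. Against the Arg library of the same run the log2 ratios of CGG and CGT were 0.47 (0.10 to 0.85) and 0.85 (0.49 to 1.21). In the CGT library 82.2% of these footprints were in the +1 frame, and 76.2% in the Arg library of that run. The reporter labelled 20-80 had 390 footprints. Position 116 held 58.6% of those in its variable segment (50.3 to 66.4), and its footprints beyond the terminal peak were 13.1% of upstream ones (8.08 to 21.4).

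Of the libraries related to the Asp and Pro reporters, both Asp codon variants held more ribosomes in the variable segment than the Asp reporter. Shares were 39.0% (37.5 to 40.6) for GAC and 56.0% (55.1 to 56.9) for GAT-GAC, against 21.9% (20.7 to 23.1) for Asp, while the terminal to upstream ratio was low in all 3, at 0.0687, 0.0684 and 0.0495. Footprints beyond the terminal peak were 2.02% of upstream ones for GAC (1.49 to 2.73), 0.678% for GAT-GAC (0.480 to 0.958) and 0.432% for Asp (0.261 to 0.713), with a log2 ratio of GAC to Asp of 2.22 (1.37 to 3.08). The Pro reporter library labelled GC7, a label whose meaning the sample labels do not give, had a share of 53.7% (52.1 to 55.3) and a terminal to upstream ratio of 0.171 (0.150 to 0.196), against 0.474 (0.441 to 0.509) for Pro. Without the top positions the GC7 share difference from Pro was 7.90 points and the log2 ratio of terminal to upstream went from -1.47 to -0.21. The Asp variants and GC7 came from different runs than their references. Of the mixed repeats, A-K peaked at position 185 (32.1% of variable-segment footprints) and K-A at position 125 (36.4%). Position 125 was the top position of the Lys reporter, but also of the Asp and Asp GAC reporters. The Q-P mix had a share of 24.5% (23.4 to 25.7).

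The reporters flanked by miRFP and EGFP contrasted Pro with Asp. On miRFP-P-EGFP a single position, 1184, held 80.0% of the variable-segment footprints (74.4 to 84.6), while on miRFP-D-EGFP the top position, 1199, held 13.5% (10.1 to 17.7). The segment took 22.5% of all footprints on the former and 30.6% on the latter, a difference of -8.18 points (-12.0 to -4.37), which was -22.2 points without the top position of each window. The libraries held 1046 and 1018 footprints. The deposited column of the Pro reporter names an eIF5A knockdown that its sample title does not, so that reporter's condition is uncertain and the 2 reporters differ in more than the repeat.

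Disomes, footprints of 2 ribosomes in contact, concentrated in the variable segment. Of 22 reporters with at least 20 disome footprints in the 3 segments, 19 had a disome share above the monosome share beyond the interval and 1, Pro, below it. On the Tyr reporter 99.5% of disome footprints (98.4 to 99.8) were in the variable segment, 70.9% of them at position 179, which was also the top monosome position. On A-K the share was 99.1% (98.9 to 99.2) with its top at position 161, upstream of the monosome top at 185. The disome top of the Arg reporter was position 116, with 41.0% of variable-segment disomes. How fragments were assigned to positions is not given, so a position may mark different sites in disome and monosome libraries. Differences between their top positions therefore do not show that ribosomes sat at different places. Only 3 of the 22 reporters had the same top position in both kinds of library, with Arg counted by the library of the same run as its disomes, whose top was 164, although 3 of the 6 Arg monosome libraries had their top at 116. Across the 22 reporters disome and monosome shares were not correlated beyond chance (Pearson r = 0.224, permutation p = 0.319; Spearman rho = 0.202, p = 0.371; r = 0.292 without the 2 reporters farthest from the median). Within the largest disome run r was 0.345 over 12 reporters (permutation p = 0.269).

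The cells' own mRNAs were used to ask which codons held ribosomes longer. Occupancy is the A-site count of a codon over that expected from its frequency in the same transcripts. In SAMD9 cells with Dox the 2 Phe codons rose above all others. TTT was 9.05-fold higher than without Dox (log2 ratio 3.18, transcript bootstrap interval 2.61 to 3.69) and TTC 8.30-fold (3.05, 2.7 to 3.43), against SDs of 0.30 and 0.35 between the 3 control libraries on the log2 scale. Per the table names, 2 of these controls belong to experiments on SAMD9 and SAMD9L, so their SD includes differences between experiments. With Dox, 51 of 61 codons lay beyond the largest difference between any 2 controls, so exceeding the control spread is not specific to Phe. The other 59 codons had a median log2 ratio of -0.46, with TCG (-1.39) and GGG (-0.99) lowest. Occupancy is relative to all counts of the same transcripts, so a rise at the Phe codons lowers the other codons by construction. A fall at those codons of its own was not tested. GTC (0.91) and CCC (0.51) came next after Phe, but their intervals ran from -2.12 to 3.13 and from -1.81 to 2.09, and a single site held 76.6% of the GTC counts.

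Without Arg the Arg codons behaved unequally. CGT was 3.43-fold higher (log2 ratio 1.78, 0.99 to 2.54) and CGC 3.33-fold (1.74, 0.77 to 2.44), AGA had a log2 ratio of 0.62 (-0.55 to 1.70), CGG 0.10 (-0.61 to 0.83) and AGG -0.03 (-0.45 to 0.39), while CGA was lower at -1.06 (-1.47 to -0.63). The 6 averaged 0.52, against a median of -0.14 over the other 55. TGT had the highest log2 ratio of all, 1.80, with an interval of -1.21 to 3.39, and 1 site carried 74.7% of its counts. AGC (1.32, 0.06 to 2.16) and GTC (1.03, -1.32 to 2.8) followed, and TCG (-1.13), CCA (-0.97), CAC (-0.89) and CCT (-0.78) were among the lowest. Of 61 codons, 42 lay beyond the largest difference between any 2 controls, so exceeding it is not specific to Arg codons. Each arm was 1 library, so these are differences between libraries. Per the table names, both Arg libraries came from cells with an Arg reporter.

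**Figure D4:**
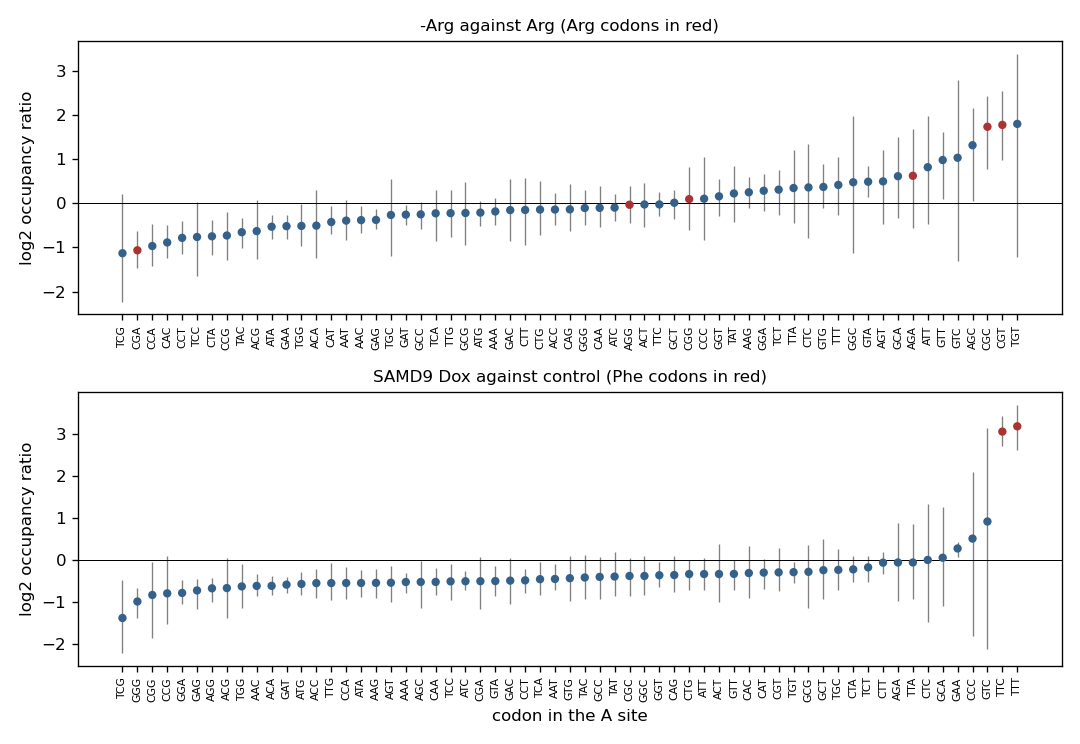
Log2 ratio of A-site occupancy for 61 codons, without against with Arg (upper panel, Arg codons in red) and SAMD9 cells with against without Dox (lower panel, Phe codons in red); bars are 95% bootstrap intervals over transcripts. TTT and TTC stand at 3.18 and 3.05, and CGT and CGC at 1.78 and 1.74.

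Around the limiting codons the density changes had different shapes, with sites capped at 20 times the transcript mean. With Dox the log2 density ratio was 2.89 with a Phe codon in the A site, 0.74 when the Phe codon was 1 codon upstream of the A site, and 0.12 when it was 1 codon downstream. Without Arg the ratio around CGC and CGT was 1.16 at the codon itself, 1.49 at 1 codon further downstream and still 0.85 at 4 codons downstream. A smaller rise of 0.39 lay 10 codons upstream of CGC and CGT, where the value for Phe with Dox was -0.15. CGC and CGT and the cap were chosen after their values were seen.

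**Figure D5:**
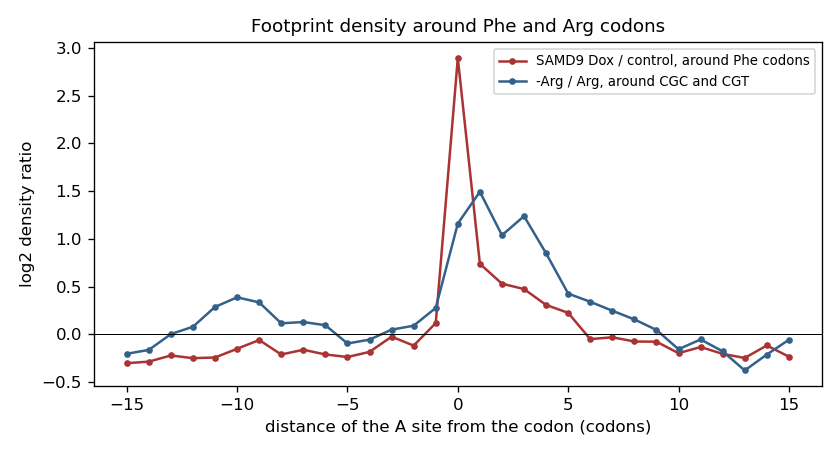
Log2 ratio of density by distance in codons from the site, with sites capped at 20 times the transcript mean, for CGC and CGT without against with Arg and for Phe codons with against without Dox. The Phe curve peaks at the A site (2.89) and the CGC and CGT curve 1 codon downstream (1.49).

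Density before and after runs of 4 or more identical amino acids was compared, as frames cannot be read from values per codon. In the 3 controls the 10 codons after a run held 1.04 ± 0.0132 (SD, n = 3) times the counts of the 10 codons before it. The ratio was 0.786 without Arg and 1.04 with Arg, and 1.93 with Dox and 1.51 without. Capping each position at 10 counts took the log2 ratio of the arms to -0.02 without against with Arg and to -0.07 for Dox. These differences thus rest on positions with more than 10 counts, and how few positions carry them was not tested. Runs of 9 amino acids reached the 1000 counts needed in each library. In the controls (SD, n = 3), Pro runs held 0.313 ± 0.154 of the expected counts, Ala runs 0.326 ± 0.0462, Ser runs 0.350 ± 0.0441 and Leu runs 0.409 ± 0.0773. Runs of the other 5 were above 1, at 1.15 ± 0.156 for Arg, 1.21 ± 0.0508 for Lys, 1.43 ± 0.131 for Val, 1.53 ± 0.270 for Glu and 2.7 ± 0.499 for Asp. This did not hold for all of them in the libraries with Arg and without Dox. There Lys runs held 0.901 and 0.130, Val runs 0.399 and 1.92, Glu runs 3.58 and 0.785 and Asp runs 1.38 and 1.37. Arg runs held 7.96 times the expected counts without Arg and 5.87 with Arg, and 7.92 with Dox and 6.84 without. After over before Arg runs, the log2 ratio without against with Arg was -1.80, not recomputed with capped positions. Changes of such size were not confined to Arg runs. The ratio was 2.83 for Ser, 1.80 for Asp, -1.38 for Pro and -1.07 for Leu, and between -0.59 (Lys) and 0.33 (Val) for the rest. Without Arg, Arg runs supplied 31837 of the 59218 counts before runs. In the SAMD9 cells, Ser runs supplied 10403 of the 21621 counts after runs with Dox and 12641 of 33160 without. Their own ratio of after to before was 7.78 with Dox and 7.98 without. The ratios over all runs in these cells thus depend strongly on Ser runs, and they were not recomputed without them.

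Transcript totals changed in many places, but so did the controls. Without Arg, 686 of 6826 transcripts were at least 2-fold higher and 1059 lower beyond the largest difference between any 2 controls, and with Dox 444 of 5603 were higher and 375 lower. Which direction held more transcripts depended on the setting, as TMM scaling gave 386 higher and 402 lower with Dox, a filter of 500 counts 93 and 135, and no filter 2706 higher and 1656 lower without Arg. Transcript ENST00000511216 had 18674 counts without Arg and 22 with it (log2 ratio of CPM plus 1, 10.04), and ENST00000314191 had 95 and 4702 (-5.10). With Dox, ENST00000379958 had 792 counts against 14 (6.25) and ENST00000367233 had 242 against 3596 (-3.25). Control replicates differed widely, with 41.1%, 34.1% and 20.3% of transcripts at least 2-fold apart in the 3 pairs and correlations of 0.669, 0.748 and 0.841, the 2 lower ones both involving replicate 1. Transcripts carried no gene names that the reference could supply, so the gene lists and SAMD9 itself were not analysed here.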

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

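Of the tests in this part, those on the terminal to upstream ratio of the Ala and Gly reporters and on the Arg footprints beyond the terminal peak were chosen after the result was seen, and capping sites was an alternative added after seeing the data. No Arg library lay apart from the other 5 in any of the 6 measures checked with Dixon's ratio.

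The Ala and Gly reporters had almost no footprints in the variable segment. Ribosomes leaving the reporter before the segment would leave few at its end. The lower of the 2 lower bounds of the terminal to upstream ratio was 0.264, which argues against the loss of nearly all ribosomes. Loss of a part stays open, as both ratios lay below the median over 20 reporters, 0.489. Fragments of the repeat that the sequence search did not place could explain the gap: the codons without any footprint made up 53.3% of the segment for Ala and 44.4% for Gly, but with 65 and 69 footprints in the segment sampling alone leaves many codons empty, so this test cannot decide and the question stays open. Fast movement through these repeats was not tested. The biological and the technical explanation cannot be told apart without the reporter sequences.

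In the run that held 18 others, the Arg reporter had more footprints beyond the terminal peak than each of them, and over all its libraries most were in the +1 frame. Outside that run the Phe reporter without Dox reached 7.92%, within the Arg range, against 2.63% in the shared run, so the level of a reporter changed with the run or the cells. For the amount, the shared run holds no difference between runs, and the Arg lower bound there, 3.98%, lay above the highest upper bound among the others, 3.79%. These are counting intervals of 1 library per reporter. The Arg libraries of all runs ranged from 3.04% to 9.68%, so variation between libraries stays open as a cause. For the frame, the lower bound of the pooled +1 share, 62.3%, argues against fragments without reading frame, which would fill the 3 frames equally. This holds only for the Arg libraries of the other runs, where the lower bound was 66.0%. In the shared run the Arg lower bound was 34.3%, close to an equal share, so the test cannot decide there. A difference between runs went with the values. The Arg +1 share in the shared run was 45.6%, not above the 50.1% of the others. It was below the 70.9% of the Arg libraries of other runs. A +1 frameshift within the Arg repeat, which could carry ribosomes past the main-frame stop, stays open as a hypothesis for the amount. It was not tested, since the reporter sequences and the frame of the next stop are unknown here.

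In the library without Arg, 3 codons that do not code for Arg (AGC, GTC and TGT) had log2 occupancy ratios above 1. A candidate explanation is that single sites hold the added counts. The median of these codons fell from 1.32 to 0.51 when each site was capped at 20 times its transcript mean. This is just above the bound of 0.5 set for the capped value, and capping itself was added after seeing the data. So single sites account for a large part, and what remains, from 0.39 to 0.61 by codon, stays open. No biological explanation was tested.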

How the results depend on the processing

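Of 145 alternatives for 49 results, 98 left the value on its side of the threshold or within its spread, and 122 were planned. Capping sites, the alternatives for frame shares, same-run or same-table Arg libraries and leaving out the column named HEK293T were chosen after seeing the data. For the values below the cause was not tested, except where fewer libraries or transcripts were used. No paired analysis was possible because the Arg, Arg IV and SAMD9 columns carry no replicate number that pairs them, and the planned leave-one-out and replicate block for SAMD9 were not run with 1 library per arm.

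Without the top position of each window, the direction of the Cys terminal to upstream log2 ratio reversed to 0.0275. The same setting took the Arg share to 49.9% and the share differences to 2.02 points for Arg withdrawal, 9.40 for Met, 4.92 for eIF5A, 14.5 for Asp GAC, 38.2 for Asp GAT-GAC, 7.90 for Pro GC7 and -22.2 for miRFP. It took the terminal to upstream log2 ratios to 0.32 for Leu, -1.35 for Met, 0.39 for Phe, 0.81 for Asp GAC, 0.92 for Asp GAT-GAC, -0.21 for Pro GC7 and 0.72 for A-K against K-A. Trimming 2 codons from each window gave 64.8 points for Lys. Leaving out the top position of each window reversed the +1 change from upstream to variable segment of Met to -10.7 points and Ile to -7.24, and gave 24.4 for Gly and -23.4 for Ser, and for the -1 change 15.2 for Gln. Leaving out the top position of the variable segment alone gave -0.327 (reversed) for Met, 3.72 for Ile and 20.3 for Gln. It gave 14.2 for Arg, where the exact test passed. The Arg top position was in the main frame in each library, so this setting raises the +1 share by construction. Without the top position of both segments the Arg gain was 7.71 points (exact sign-flip p = 0.125).

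Density after over before runs moved in the controls to 1.09 with 20 codons on each side, 1.14 with the cap of 10 counts and 1.02 for runs of 5. The log2 ratio for Arg withdrawal became -0.25, -0.0158 and -1.54 under these settings. For Dox it became 0.0485 and 0.0829 with 20 codons and runs of 5, and reversed to -0.0695 with the cap. With the P-site codon the Phe mean log2 ratio was 0.64. Without control replicate 1 the median SD of log2 occupancy was 0.0577.

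Transcript counts depended on the filter. With 500 counts required, 217 were higher and 444 lower without Arg, and 93 and 135 with Dox. With no filter these were 2706 and 1656, and 1371 and 1193.

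With each library left out in turn, the Arg share ranged from 35.9% to 41.6%, the Arg footprints beyond the terminal peak from 5.13% to 6.46%, the Arg variable to upstream density from 0.379 to 0.501 and the control run ratio from 1.04 to 1.05. The median control SD ranged from 0.0577 to 0.123. Arg IV minus Arg ranged from -11.7 to -5.38 points in share and from 0.324 to 0.523 in the terminal to upstream ratio, both extremes with 1 Arg IV library left, when the exact test can no longer pass. Depth limits what the small libraries can show, among them 20-80 with 390 footprints, Arg replicate 5 with 640 and the disome libraries with a median of 82.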

Other observations

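The tests on counts upstream of the midpoint were put in their present form after their results were seen, as were the capped values. The test on identical codons was written beforehand, but the allowance for the spread between controls was added to it after its value was seen.

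A hypothesis taken from the series title was that A-site occupancy depends on whether the preceding codon is identical or only synonymous. The test required a median log2 difference of at least 0.1 in size and of the same sign in all 3 controls. The medians were -0.13, -0.12 and -0.0873 (58, 55 and 48 codons), so the third missed the bound, and by the test as first written the hypothesis failed. The shortfall is smaller than the spread between the controls, which leaves the question open. The direction was towards fewer counts after an identical codon, the opposite of slower decoding.

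Another hypothesis was that ribosomes gather towards the start of coding sequences when a tRNA or amino acid is short. Upstream of the midpoint lay 53.3% of counts without Arg, against 49.0% with Arg and 49.4% to 49.7% in the controls, and 55.6% with capped sites, so both values went with the hypothesis. With Dox the share was 48.6%, against 48.8% without Dox, which goes against it. With capped sites the share was 52.6% against 49.7%, and 1 site held 4.20% of the Dox library. As first written, without the cap, the test went against the hypothesis for Dox; requiring both values to point the same way came later, and leaves it open.

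In-frame TGA codons inside the listed coding sequences carried 106 to 7572 counts per library. Their occupancy was 3.04 in control replicate 1 with 7572 counts, and 13.8 and 19.5 in replicates 2 and 3 with 322 and 288 counts. Occupancy was 1.65 with Dox against 2.65 without Dox, and 1.11 without Arg against 0.885 with Arg, both pairs below the 3 controls. Occupancy did not rise with the counts and differed widely between the controls, so a difference between these pairs and the controls cannot be read from it.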
